A study of Homo sapiens with 7 samples.

How the data were processed

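Genomic DNA of 7 HUES64 libraries was sheared, ligated to methylated adapters, bisulfite converted and sequenced, per the labels' protocols. Reads were aligned with BSMAP 2.7 to hg19 (GRCh37), per the submitters' processing notes. How methylation was called, and whether duplicates, overlapping mates or read ends were removed, is not given in the sources used here. Unconverted cytosines would raise and trimmed or filtered reads would shift every level of a library, and no conversion rate was used here.

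Each deposited file lists 1 CpG per line with its position, a field that gives methylated reads and all reads, and a score. The deposited score equals 1000 times the methylated share of reads, rounded, in all lines of all files (0 lines differed). The deposited read pair is neither a fraction nor a plain count, and was split into its 2 whole numbers. Positions are given 1-based in hg19. Files list only CpGs with at least 1 read. The authors' files had 27146126 to 27657711 listed CpGs per library. Chromosome Y was left out.

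Groups came from the sample titles, 1 library per group, so no replicate could be compared, averaged or left out. For 1 library the title said DNMT3B knockout at late passage and the source name and genotype tag said DNMT3A knockout. The title was followed, and the early DNMT3B knockout library was put in its place as an alternative. The passage of the CD184 library was not given in its labels. Knockouts could not be checked from a deleted sequence, since the files hold methylation calls only.

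Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used. For the pooled level, reads were summed over autosomal CpGs with at least 5 reads in all 7 libraries. Levels have 95% Wilson intervals, and the 11 pooled differences have intervals from the same binomial counts and two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 11 comparisons. Tiles were 1 kb windows with at least 3 such CpGs, 383857 on autosomes and 1392 on chromosome X. Each was tested with a two-sided Fisher's exact test on summed reads, adjusted over tiles, and counted as lower or higher at an adjusted p below 0.05 and a difference of at least 20 percentage points. The median tile had 27 or 28 reads in the early libraries, 40 to 54 in the late ones and 63 in the CD184 library. Tested on simulated tiles at the depths of the late and early double knockout, the procedure recovered 7% of 100 tiles lowered by 30 points and 43% of 100 lowered by 50 points, with 1 false call among 385249 tiles. At the depths of the early DNMT3B and DNMT3A knockouts it recovered 6% and 29%. With more changed tiles the adjustment is less strict, so these shares do not give the recovery in comparisons with many calls, and the other 9 comparisons were not simulated. Simulated reads were independent, and unchanged tiles had the same level in both libraries. The count of false calls therefore gives no false call rate for real libraries.

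Region classes came from CpG positions alone. Density classes divided tiles at 10, 20, 40 and 60 listed CpGs per kb. Pericentromeric meant within 2 Mb of the longest stretch without a listed CpG, and subtelomeric within 1 Mb of the first or last listed CpG. On chromosomes 13, 14, 15, 21 and 22 the stretch before the first listed CpG was used, so some CpGs there counted in both classes. Means over CpG levels used CpGs with at least 1 read in all 7 libraries. Tile sets chosen in some libraries were described in the others. The named regions follow a rule fixed before the data were examined: for each comparison, up to 3 runs of adjacent lower tiles and 3 of higher tiles with the most tiles, joined over gaps of 1 tile, of which the text gives some.

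No hg19 annotation was used here, and the gene table that was at hand gives another assembly (GRCh38.p14), so no coordinates were matched to genes. Promoter counts, tests of gene lists and gene names for regions were therefore not run. Alternatives were coverage minimums of 1 and 10 reads, unweighted means, CpGs covered in the compared libraries only, chromosome X, other tile thresholds, thinning of all libraries to the depth of the shallowest, tiles at their mean depth per CpG, and wider region classes. Unweighted means at 1 read, removal of the 1328 tiles over 4 times the median depth, removal of pericentromeric tiles, subtelomeric classes without the first CpGs of chromosomes 13, 14, 15, 21 and 22, and odds ratios of location matched on reads were chosen after seeing the data. The matched odds ratios are Mantel-Haenszel ratios over 52 groups of tiles early and 68 late, cut by the reads of the shallower of the 2 libraries.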

Results

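Whole-genome bisulfite sequencing measured CpG methylation in HUES64, an established human embryonic stem cell line, after knockout of the de novo DNA methyltransferase genes DNMT3A, DNMT3B or both. The 7 libraries comprised an early and a late passage library of each genotype and 1 library of DNMT3A knockout derived cells labelled CD184. CD184 is CXCR4, a surface marker used to isolate definitive endoderm, while a cell line tag of this library reads ES, so the labels do not settle what the cells were. Each group held 1 library, so no spread between replicates could be measured, and every test below compares 2 libraries, not 2 conditions. The early libraries carried the passage labels 24 plus 7 for the DNMT3A knockout, 24 plus 6 for the DNMT3B knockout and 24 plus 5 plus 2 for the double knockout. The late ones carried 24 plus 22 for both single knockouts and 24 plus 5 plus 17 for the double knockout. The late library titled DNMT3B knockout had a source name and a genotype tag that said DNMT3A knockout. The title is followed below, so the late DNMT3B knockout means the late library so titled, whose genotype its own labels dispute. Wild-type cells were not analysed here.

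The early DNMT3A, DNMT3B and double knockout libraries held 136355417, 143907358 and 130287234 reads over CpGs. Their late counterparts held 305618221, 257651063 and 208237657, and the CD184 library held 330946628. The median depth per listed CpG was 5, 5 and 4 reads in the early libraries, 10, 9 and 7 in the late ones, and 11 in the CD184 library. Levels were pooled over the 2909763 autosomal CpGs with at least 5 reads in all 7 libraries, and tests used 385249 tiles of 1 kb. Intervals are nominal 95% intervals that cover counting error only, except the bootstrap intervals among the other observations, which resample tiles. The counting intervals treat every CpG call as independent. Reads that span several CpGs count more than once, so these intervals are too narrow.

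The 4 early and late single knockout libraries stayed highly methylated, and the double knockout was lower at both passages. The pooled level was 83.40% (83.38 to 83.41) in the early DNMT3A knockout, 82.08% (82.07 to 82.10) in the early DNMT3B knockout and 77.62% (77.60 to 77.64) in the early double knockout. At late passage it was 84.02% (84.01 to 84.03), 82.45% (82.44 to 82.46) and 71.43% (71.42 to 71.45), and it was 82.92% (82.91 to 82.93) in the CD184 library. As an unweighted mean over 23964493 autosomal CpGs with at least 1 read in each library, an alternative chosen after seeing the data, the late levels were 82.7%, 81.6% and 69.5% and the early ones 80.8%, 80.7% and 74.97%. CpGs below 20% methylation made up 8.72% of the early and 13.7% of the late double knockout, against 4.23% to 5.29% in the other 5 libraries. By the mean over CpGs with at least 1 read the level fell with CpG density in every library, and the 2 double knockout libraries were lowest in all 5 density classes. Pooled over CpGs with at least 5 reads, the CD184 library had 85.9% and 86.0% in the 2 sparsest classes, and the late library titled DNMT3B knockout (48.2%) lay below the early double knockout (48.7%) at 60 or more CpGs per kb.

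**Figure D1:**
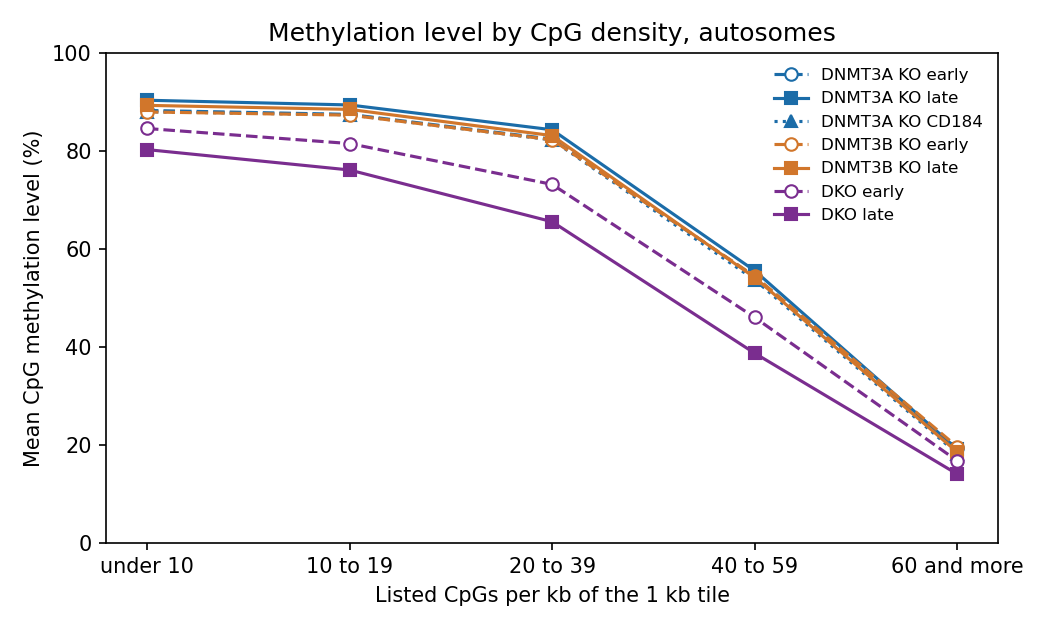
Mean CpG methylation level in percent (vertical axis) of each of the 7 libraries over autosomal CpGs with at least 1 read, against the density of listed CpGs in the 1 kb tile (horizontal axis). Open circles with dashed lines are early, filled squares with solid lines late and triangles with dotted lines CD184 libraries. In tiles of 20 to 39 CpGs per kb the late double knockout lay at 65.5%, below 73.2% in the early double knockout and 84.3% in the late DNMT3A knockout.

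The first comparison asked whether the level changed between early and late passage in each genotype. The late double knockout library was lower than the early one across the genome. The pooled level of the double knockout fell by 6.19 percentage points (interval -6.21 to -6.16), from 77.6% to 71.4%. The unweighted mean went from 74.97% to 69.51%, so the late library had 92.7% of the early level, with 15 passages between the labels. That would be a loss of 0.503% of the level per passage if the whole fall came from passage and was even. The mean level was lower in 22 of 22 autosomes, with a change of -8.31 points on chromosome 22 and -4.27 on chromosome 4 as the extremes. In the single knockouts the pooled level rose by 0.624 points (0.605 to 0.643) for DNMT3A and by 0.363 points (0.343 to 0.383) for the libraries titled DNMT3B.

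The falls in the double knockout were spread over 15174 tiles that were lower in the late library, against 888 that were higher. In the lower tiles its level went from 67.7% to 30.6%, while the DNMT3A knockout stood at 82.0% early and 83.2% late, and the DNMT3B knockout at 80.6% and 80.3%. The longest run of lower tiles covered 45 tiles and 1324 CpGs on chromosome X from 114959001 to 115004000 (hg19). There the double knockout went from 80.3% of 10263 reads to 20.9% of 28628 reads, and the other 5 libraries lay between 94.8% and 95.9%. Next came chromosome 16 from 15013001 to 15021000, with 61.7% of 700 reads and 22.4% of 1714 reads, and chromosome 10 from 1230001 to 1238000, with 65.4% of 182 reads and 8.8% of 294 reads.

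Few tiles changed between passages in the single knockouts. In the DNMT3A knockout 186 tiles were lower and 1507 higher at late passage, and in the library titled DNMT3B knockout 316 were lower and 848 higher. Thinned to one depth, 79 and 164 were lower and 498 and 302 higher. Overlapping runs on chromosome 5 that start at 99382001 were among the longest higher runs in all 3 genotypes. In the 7 tiles called there in the double knockout, the early libraries lay between 29.5% and 33.5%, and the late ones 88.1%, 88.2% and 88.3%. Depth differed there too. From 99382001 to 99391000 the early DNMT3A, DNMT3B and double knockouts had 2.33, 1.86 and 2.31 times their median depth per CpG. The late ones had 1.41, 1.05 and 1.05 times theirs. Extra unmethylated reads from another copy in the early libraries may thus explain the rise, which was not tested for this run alone. Higher tiles shared by both single knockouts numbered 232, where 3.32 would be shared by independent lists, a number not matched on level or reads. A run of 4 tiles on chromosome 1 from 1222001 to 1226000 was lower in the late library titled DNMT3B knockout than in the early one. It went from 55.1% of 1147 reads to 21.8% of 2484 reads, with 96.6% and 95.2% in the DNMT3A knockout. The double knockout fell there too, from 82.6% to 40.9%. The pooled rise of both single knockouts turned into a fall when reads were pooled over CpGs with at least 1 read (-5.39 points for DNMT3A and -2.92 for DNMT3B) or over the CpGs covered in both libraries (-1.44 and -0.538). For DNMT3B it also turned at a minimum of 10 reads (-0.114). Counting each tile only at its mean depth per CpG left 2 lower tiles in the double knockout. That setting leaves few reads per tile, with a mean per CpG of 7.63 in the early and 11.5 in the late double knockout. Its tests can hardly pass the threshold whatever the difference, so this count says little about the change. A coverage minimum of 1 read gave 112872 lower of 2321750 tested tiles in the double knockout (4.86%, against 3.94%).

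**Figure D2:**
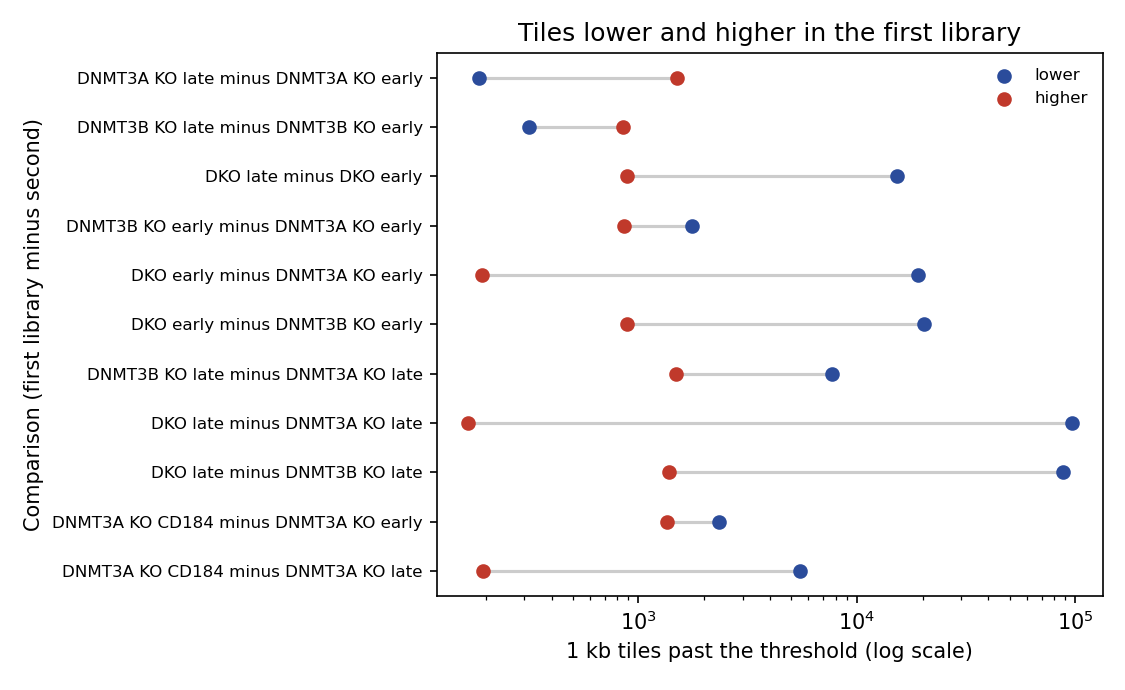
Number of 1 kb tiles past the threshold (horizontal axis, log scale) that were lower (blue) or higher (red) in the first library of each of the 11 comparisons (vertical axis). Lower tiles ranged from 186 in the late against the early DNMT3A knockout to 96718 in the late double knockout against the late DNMT3A knockout.

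The second comparison set the DNMT3B knockout against the DNMT3A knockout, which asks where loss of one enzyme differs from loss of the other. Genome-wide the libraries were close, and the DNMT3B knockout was lower near centromeres. The pooled early difference was -1.32 points (-1.34 to -1.29) and the late one -1.58 points (-1.59 to -1.56). As an unweighted mean the early difference was -0.506 points at a minimum of 5 reads and -0.157 at 1 read, and the mean was lower on 15 and higher on 7 of 22 autosomes early, and lower on all 22 late. Within 2 Mb of the longest stretch of each chromosome without CpGs, which marks the centromere region, the mean CpG level was 79.3% in the early DNMT3A knockout and 73.8% in the early DNMT3B knockout. At late passage it was 81.4%, and 72.9% in the library titled DNMT3B knockout. This pericentromeric level was lower in the DNMT3B knockout on 22 of 22 autosomes at both passages, by a median of -6.26 points early and -9.10 points late. The extremes were chromosome 21, with -15.3 and -23.0 points, and chromosome 3, with -0.570 and -1.01 points.

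Of the tiles tested, 1760 were lower and 856 higher in the early DNMT3B knockout than in the early DNMT3A knockout. Late, 7676 were lower and 1483 higher in the library titled DNMT3B knockout, in deeper libraries. Thinned to one depth, 1664 were lower early and 3660 late, with 44.1% of the 7676 among the latter. Of the early lower tiles, 1248 (70.9%) were lower late as well, where independent lists would share 35.1, and of the early higher tiles 325 (38.0%), where 3.30 would be shared. These early and late comparisons share no library, and the shared counts were not matched on level or reads. Among the 1760 lower tiles 37.4% were pericentromeric, against 3.47% of all tested tiles (odds ratio 17.4), and 15.5% lay within 1 Mb of a chromosome end, against 3.95% (odds ratio 4.52). Tiles over 4 times the median depth were enriched too, at 3.52% against 0.345% (odds ratio 11.02). Matched on reads per tile, an alternative chosen after seeing the data, the 2 location odds ratios were 6.65 and 2.40. Without the first CpGs of chromosomes 13, 14, 15, 21 and 22, also chosen after seeing the data, the one for chromosome ends was 2.02, or 1.22 when matched, and the early difference near chromosome ends, pooled at 5 reads, went from -3.97 to -1.99 points. Of the 856 higher tiles 32.1% had 40 or more CpGs per kb, and of the lower ones 10.7%, against 5.27% of tested tiles (odds ratios 8.60 and 2.16). The density ratios were not matched on reads and are not particular to this comparison. Tiles lower in the late than the early DNMT3A knockout had 10.6, while tiles lower in the CD184 library than in both DNMT3A knockout libraries had 0.611. Neighbouring tiles are not independent, so these shares carry no p-value.

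The longest lower run at late passage covered 47 tiles and 909 CpGs on chromosome 1 from 2584001 to 2634000. The DNMT3A knockout had 64.6% of 16852 reads early and 65.5% of 77738 reads late, and the DNMT3B knockout 40.8% of 18401 and 33.9% of 53400. Its depth was 4.09 times the median of tested tiles. The next 2 runs lay in the pericentromeric part of chromosome 21, from 10815001 to 10863000 with 41 tiles and from 10784001 to 10813000 with 23 tiles. In the first of them the DNMT3A knockout had 78.7% early and 81.7% late, and the DNMT3B knockout 61.7% and 52.0%. Higher runs in the DNMT3B knockout included chromosome 3 from 112137001 to 112142000, with 21.3% and 15.6% in the early and late DNMT3A knockout and 76.8% and 86.2% in the DNMT3B knockout. Another lay on chromosome 4 from 13536001 to 13545000, with 13.5% and 4.9% against 45.7% and 39.7%. In both runs the late double knockout was the lowest library, at 1.8% and 0.8%. The late pooled difference turned to 2.27 points at a minimum of 1 read and to 2.32 points over the CpGs covered in both libraries. Lower tiles numbered 964 early and 4837 late without pericentromeric tiles, an alternative chosen after seeing the data. With each tile at its mean depth per CpG they numbered 0 and 139. The early count was nearly fixed in advance, since so few reads per tile can hardly pass the threshold.

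**Figure D3:**
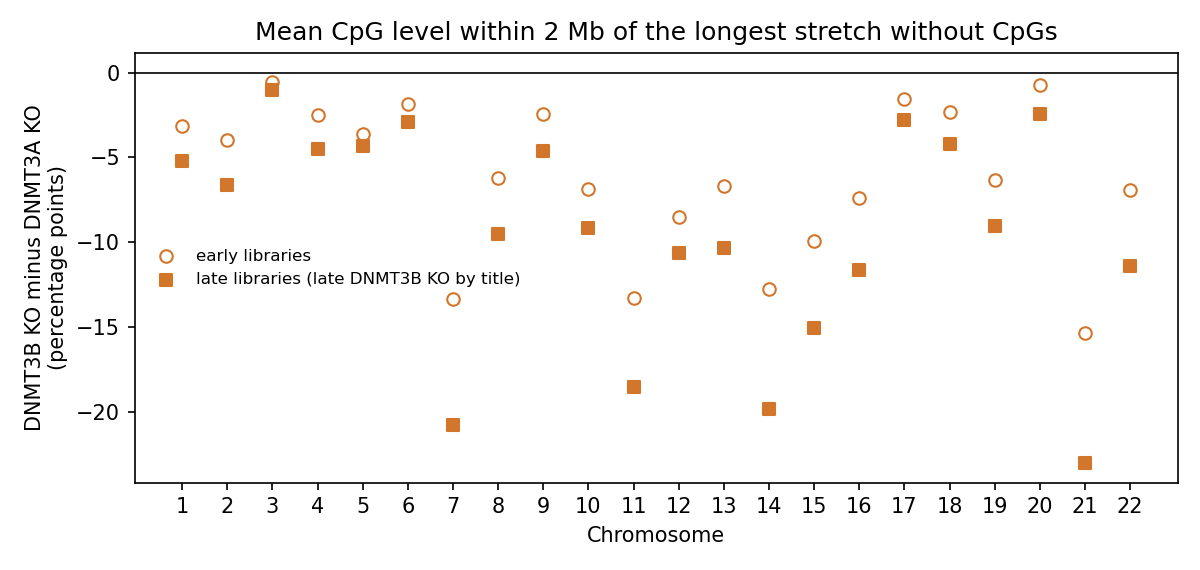
Mean CpG level of the DNMT3B knockout minus that of the DNMT3A knockout in percentage points (vertical axis), within 2 Mb of the longest stretch without CpGs on each autosome (horizontal axis). Open circles are early and filled squares late libraries. All points lie below 0, from -0.570 on chromosome 3 early to -23.0 on chromosome 21 late.

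The third comparison set the double knockout against each single knockout and asked what is lost only when both enzymes are absent. At early passage the double knockout was lower than the DNMT3A knockout by -5.78 points (-5.80 to -5.76) and than the DNMT3B knockout by -4.47 points (-4.49 to -4.44). At late passage the differences were -12.59 points (-12.61 to -12.57), and -11.02 points (-11.03 to -11.00) from the library titled DNMT3B knockout. All 22 autosomes were lower in each of these 4 comparisons, with the most negative mean difference on chromosome 22 (-18.97 points against the late DNMT3A knockout). Against the DNMT3A knockout 19104 tiles were lower and 193 higher early, and 96718 (25.1%) lower and 165 higher late. Against the DNMT3B knockout 20331 were lower and 882 higher early, and 88035 lower and 1375 higher against the late library so titled.

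Early, 11326 tiles were lower in the double knockout than in both single knockouts, 2 comparisons that share the double knockout library. The double knockout had 31.9% there, and the early DNMT3A and DNMT3B knockouts had 76.5% and 78.1%. In the late libraries, which played no part in choosing these tiles, the levels were 19.1%, 76.8% and 76.8%, and 94.2% of the tiles were lower than in both late single knockouts, against 19.7% of all tested tiles. Only 1.33% of these tiles were pericentromeric, against 3.47% of tested tiles (odds ratio 0.369). The DNMT3B knockout was already lower near centromeres, so the rule for this set partly shuts such tiles out. Among the 19104 tiles lower than in the early DNMT3A knockout alone, the share was 1.94% (odds ratio 0.537). The longest early runs included chromosome 16 from 15012001 to 15020000, with 56.0% of 645 reads against 87.7% of 684 reads in the DNMT3A knockout. They also included chromosome 9 from 129286001 to 129292000, with 17.8% of 197 reads against 80.6% of 201 reads.

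Of the 882 tiles in which the early double knockout was higher than the early DNMT3B knockout, 45.0% were pericentromeric (odds ratio 23.5, not matched on reads). This set rests on the same early DNMT3B knockout library as the tiles lower there than in the early DNMT3A knockout. Its location is therefore not separate evidence. Their levels, of which the DNMT3B and double knockout ones were used to choose them, were 73.1% in the DNMT3A knockout, 43.5% in the DNMT3B knockout and 73.7% in the double knockout. The late libraries had 74.8%, 43.5% and 61.1% in these tiles. On chromosome 1 from 142653001 to 142659000 the early levels were 71.0%, 37.0% and 65.1%. The pooled difference from the DNMT3B knockout turned at a minimum of 10 reads (4.34 points early and 2.37 late), a setting that kept 78564 autosomal CpGs. Early, it also turned on chromosome X (0.900 points over 12213 CpGs). The unweighted mean over those X CpGs did not turn, at 75.4% in the early double knockout and 81.5% in the early DNMT3B knockout. With each tile at its mean depth per CpG, lower tiles numbered 0 in both early comparisons, and 14218 and 9823 late against the DNMT3A and DNMT3B knockouts. The early counts were nearly fixed in advance by the few reads left per tile.

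**Figure D4:**
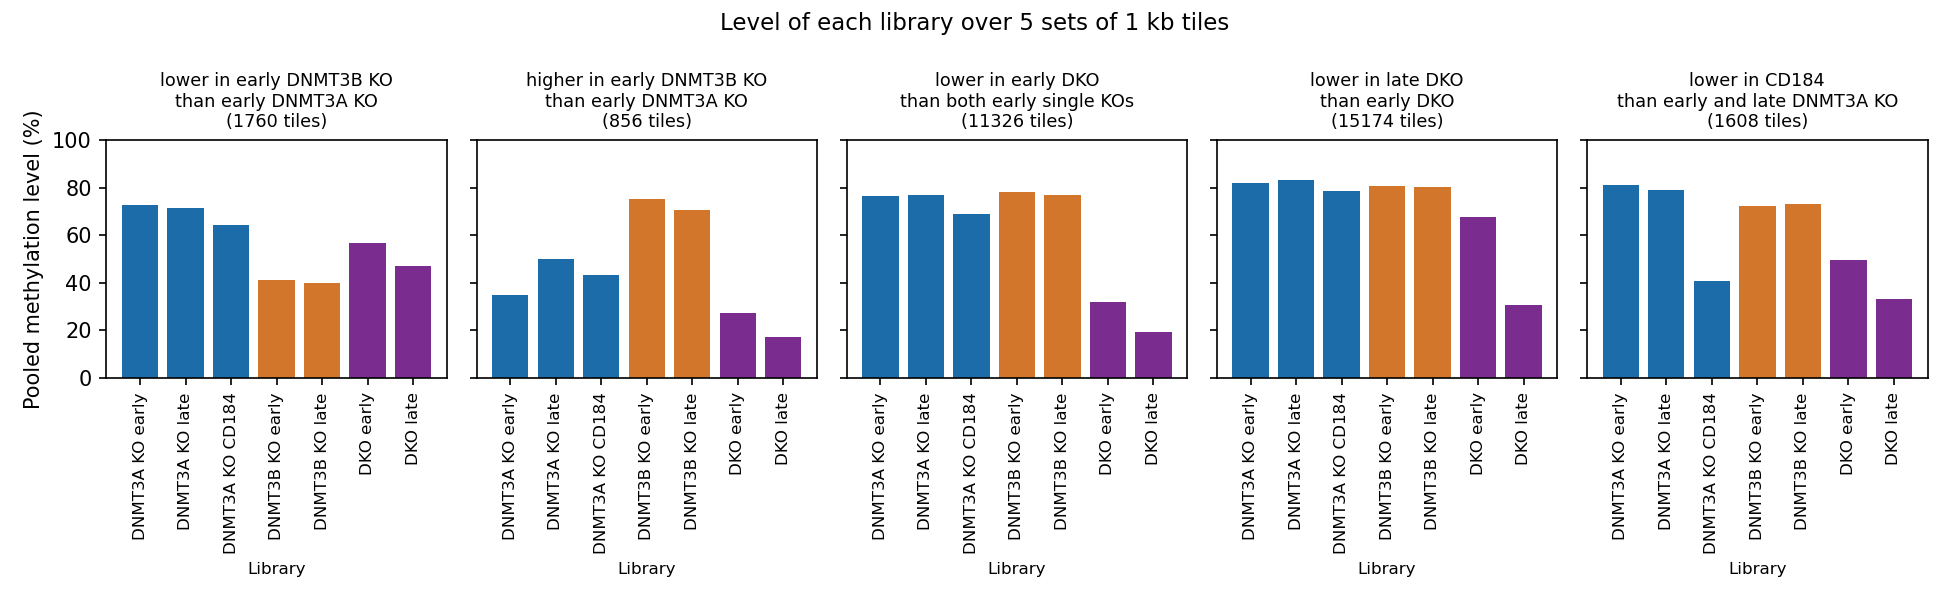
Pooled methylation level in percent (vertical axes, bars from 0) of the 7 libraries (horizontal axes) in 5 sets of tiles, named above each panel with the number of tiles. Bars are blue for DNMT3A knockout, orange for DNMT3B knockout and purple for double knockout. In the 11326 tiles lower in the early double knockout than in both single knockouts, the late double knockout stood at 19.1%.

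The fourth comparison set the CD184 library against the early and late DNMT3A knockout libraries. Its pooled level was close to theirs, at -0.479 points (-0.497 to -0.461) from the early and -1.10 points (-1.12 to -1.09) from the late library. Tiles lower in the CD184 library numbered 2348 against the early and 5479 against the late library, and higher ones 1350 and 194. Thinned to one depth, 1035 and 1244 were lower and 351 and 30 higher, and 40.9% of the 2348 and 20.9% of the 5479 lower tiles were among them. Passing both comparisons, which share the CD184 library, were 1608 lower tiles and 15 higher ones. In the 1608 tiles the level was 40.8% in the CD184 library, 80.9% and 79.1% in the early and late DNMT3A knockout, and 72.2% and 73.2% in the DNMT3B knockout. The double knockout, which was not used to choose them, had 49.4% early and 33.1% late.

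Runs lower in the CD184 library included chromosome 1 from 8181001 to 8183000, with 16.7% of 168 reads against 94.6% of 56 reads in the early and 79.6% of 113 reads in the late DNMT3A knockout. On chromosome 9 from 129281001 to 129284000 it had 41.9% of 346 reads, against 73.4% of 128 reads early and 48.1% of 237 reads late. On chromosome 12 from 4128001 to 4132000 it had 37.9% of 554 reads, near the early level of 44.0% of 218 reads and below the late level of 74.5% of 620 reads. The pooled difference from the late library turned to 3.23 points at a minimum of 1 read and to 3.12 points over CpGs covered in both libraries. That from the early library was 0.0770 points on chromosome X, too small to tell from no difference. With each tile at its mean depth per CpG, 2 and 0 tiles were lower against the early and late libraries. That setting leaves too few reads per tile to call most differences.

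Two-sided Fisher's exact tests on pooled reads gave an adjusted p of 6.33e-292 for late minus early in the DNMT3B knockout and a value too small for the computation to hold in the other 10 comparisons. Reads that span several CpGs are counted more than once, so these p-values and the tile tests are too small.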

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

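The test of a technical difference between early and later libraries was chosen only after the result was seen, and the depth test was fixed before. The change from early to late passage went in opposite directions between genotypes. The double knockout fell by 6.19 points, and both single knockouts rose, by 0.624 points for DNMT3A and 0.363 points for DNMT3B. Its change minus theirs was -6.81 points against the DNMT3A knockout and -6.55 points against the DNMT3B knockout. When reads were pooled over CpGs with at least 1 read, all 3 genotypes fell, with -5.39 points for DNMT3A, -2.92 for DNMT3B and -10.5 for the double knockout. The difference between genotypes was not tested, since each rests on 1 early and 1 late library.

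An overall depth difference between the double knockout libraries does not account for most of their 15174 lower tiles. After all libraries were thinned to one depth, 10113 tiles were lower, 9320 of them (61.4%) among the 15174. Thinning took a single share of reads per library, so depth differences between places in the genome were not tested. A technical difference between the early and the later libraries as a whole would be expected to lower the 15174 tiles in the single knockouts too. Over these tiles the median late minus early difference was 1.48 points in the DNMT3A knockout and 0.447 points in the DNMT3B knockout, against -38.7 points in the double knockout. Loss of methylation over passages without both enzymes may explain the fall and stays open as a hypothesis, as does a difference between the 2 double knockout cultures themselves. A second library per group would be needed to tell these apart.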

How the results depend on the processing

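Results were recomputed under each alternative for the comparisons it applies to: all 11, except that the early DNMT3B library in place of the late one changes 2, and matching on reads per tile was done for early and late DNMT3B minus DNMT3A. The 5 alternatives named as later choices in the methods were picked after seeing the data. Of the pooled differences, 55 kept their direction and 13 turned. Late minus early turned in the DNMT3A knockout at 1 read (-5.39) and over CpGs covered in both libraries (-1.44), and in the DNMT3B knockout at 1 read (-2.92), over CpGs covered in both (-0.538) and at 10 reads (-0.114). The late DNMT3B minus DNMT3A difference turned at 1 read (2.27) and over CpGs covered in both (2.32), and CD184 minus late DNMT3A likewise (3.23 and 3.12). Depth may explain the turn at 1 read in late minus early DNMT3A. Mean reads per CpG went from 7.72 in tiles under 10 CpGs per kb to 21.2 in those of 60 or more in the late DNMT3A library. In the early one they went from 5.38 to 3.77, so that weakly methylated tiles weigh more in the late library. Depth by density is not given here for the other comparisons that turned. Unweighted means over the same CpGs kept the direction of all 11 differences. With the early DNMT3B library in place of the late one, late DNMT3B minus DNMT3A was -1.94 and double knockout minus DNMT3B -10.7 (no direction changed). Double knockout minus DNMT3B turned at 10 reads (4.34 early, 2.37 late), over 78564 CpGs, and, early, on chromosome X (0.900, pooled over 12213 CpGs). Unweighted over those X CpGs it did not turn, with 75.4% in the double knockout against 81.5%. CD184 minus early DNMT3A turned on chromosome X (0.0770), a value too small to tell from no difference. The cause of the turns at 10 reads was not tested. Each group has 1 library, so none could be left out. Promoter counts and list shifts were not run for want of an hg19 annotation here.

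Tile counts are listed in one order: late minus early in the DNMT3A, DNMT3B and double knockouts, then early DNMT3B minus DNMT3A, double knockout minus DNMT3A and double knockout minus DNMT3B, the same 3 at late passage, and CD184 minus early and minus late DNMT3A. As reported, lower tiles numbered 186, 316, 15174, 1760, 19104, 20331, 7676, 96718, 88035, 2348 and 5479, and higher tiles 1507, 848, 888, 856, 193, 882, 1483, 165, 1375, 1350 and 194. At a coverage minimum of 1 read, lower tiles numbered 3266, 3851, 112872, 8704, 119377, 120385, 31103, 435625, 406173, 19505 and 25777, and higher tiles 5570, 3132, 2623, 5005, 1176, 4785, 5214, 607, 6133, 4186 and 1176. At a minimum of 10 reads, lower tiles numbered 29, 84, 330, 605, 193, 194, 1275, 1175, 519, 82 and 118, and higher tiles 186, 130, 117, 28, 9, 264, 26, 9, 166, 162 and 15. With a difference of at least 10 points, lower tiles numbered 326, 546, 16609, 2491, 19994, 21199, 10272, 116902, 103780, 2708 and 7271, and higher tiles 1941, 1031, 1143, 913, 257, 1432, 1940, 447, 2478, 1813 and 428. With at least 30 points, lower tiles numbered 104, 184, 11843, 1239, 16546, 17604, 4781, 68718, 63834, 1848 and 3285, and higher tiles 807, 477, 432, 721, 99, 475, 907, 39, 628, 638 and 66. With each tile at its mean depth per CpG, lower tiles numbered 2, 1, 2, 0, 0, 0, 139, 14218, 9823, 2 and 0, and higher tiles 2, 0, 0, 0, 0, 0, 30, 0, 26, 4 and 0. At this setting tiles of the early libraries keep so few reads that calls were nearly impossible. Its counts therefore do not test comparisons that use an early library. After thinning to one depth, lower tiles numbered 79, 164, 10113, 1664, 18744, 19593, 3660, 67540, 62914, 1035 and 1244, and higher tiles 498, 302, 482, 794, 195, 856, 649, 112, 879, 351 and 30. With at least 5 CpGs per tile, lower tiles numbered 211, 349, 10487, 1586, 11965, 12602, 4601, 39210, 35993, 1606 and 2724, and higher tiles 1428, 812, 691, 803, 164, 725, 959, 58, 677, 1026 and 142. The tiles tested numbered 385249 as reported, 2321750 at a minimum of 1 read, 6918 at 10 reads, 146142 with at least 5 CpGs and 371897 without pericentromeric tiles, so counts under these settings have other totals: higher tiles in late minus early DNMT3A were 0.391% of tested tiles as reported and 0.240% at 1 read. Without pericentromeric tiles, lower tiles fell to 964 early and 4837 late in DNMT3B minus DNMT3A, and higher tiles to 477 early and 860 late in double knockout minus DNMT3B. With the unweighted mean of CpG levels for the difference, higher tiles in CD184 minus late DNMT3A fell to 119. Lower minus higher tiles turned in 5 cases: late minus early DNMT3B at 1 read (719) and at mean depth (1), early double knockout minus DNMT3B at 10 reads (-70), and CD184 minus early DNMT3A at 10 reads (-80) and at mean depth (-2); the cause was not tested.

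Pericentromeric differences in points, pooled over CpGs with at least 5 reads and in the same order, were 1.16, -0.613, -2.98, -7.81, -2.98, 4.82, -9.58, -7.12, 2.46, -2.69 and -3.86 within 2 Mb and 0.920, -0.406, -3.78, -6.19, -3.63, 2.56, -7.51, -8.33, -0.818, -2.13 and -3.05 within 5 Mb. Subtelomeric differences, pooled likewise, were 1.40, 0.128, -5.99, -3.97, -6.29, -2.33, -5.24, -13.7, -8.45, 0.685 and -0.715 within 1 Mb, 1.11, -0.168, -7.78, -3.11, -7.45, -4.34, -4.39, -16.3, -11.9, -0.221 and -1.34 within 3 Mb, and 2.71, 1.08, -5.63, -1.99, -6.78, -4.79, -3.62, -15.1, -11.5, 1.67 and -1.04 without the first CpGs of chromosomes 13, 14, 15, 21 and 22. The late double knockout minus DNMT3B turned near centromeres, and late minus early DNMT3B and CD184 minus early DNMT3A turned near chromosome ends within 3 Mb; the cause was not tested. The same 3 turned as unweighted means at 5 reads, to -1.06 within 2 Mb of centromeres and -0.196 and -0.815 within 1 Mb of chromosome ends. Among tiles lower in DNMT3B minus DNMT3A, the odds ratio of pericentromeric tiles moved from 17.4 to 6.65 early and from 15.9 to 10.2 late when matched on reads per tile, and that of subtelomeric tiles from 4.52 to 2.40 and from 5.26 to 3.54. Without the first CpGs of chromosomes 13, 14, 15, 21 and 22 the latter were 2.02 and 2.44.

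With 100 tiles lowered by 50 points, 29% were recovered at the depths of the early DNMT3B and DNMT3A knockouts and 43% at those of the double knockout libraries.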

Other observations

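All tests in this part were chosen only after the results were seen, except the first test of the late library titled DNMT3B knockout. Tile sets chosen without a shared library overlapped more than independent lists would. Of the 5479 tiles lower in the CD184 library than in the late DNMT3A knockout, 1717 (31.3%) were also lower in the early double knockout than in the early DNMT3B knockout, where 289 were expected. Of the 2348 tiles lower in the CD184 library than in the early DNMT3A knockout, 1490 (63.5%) were also lower in the late double knockout than in the late library titled DNMT3B knockout, where 537 were expected. Both pairs set tiles low in CD184-labelled DNMT3A knockout cells beside tiles low in stem cells without either enzyme. The expected counts treat all tiles as equally callable, which they were not. Early double knockout minus DNMT3B had 23.3% lower tiles at 20 to 50% in the early DNMT3A knockout, and 3.11% at 80 to 100%. By level in the early DNMT3B knockout, CD184 minus late DNMT3A had 5.61% and 0.872%. The lists were not matched on level or reads, so these overlaps do not show that the cells resemble each other.

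The region on chromosome X from 114959001 to 115004000 and that on chromosome 1 from 2584001 to 2634000 had repeated CpG spacing. On chromosome X, 28.6% of listed CpGs had another at a distance of 5962 bp, against a median of 6.11% over distances from 500 to 10000 bp. On chromosome 1 the distance was 4616 bp, with 23.8% against 2.29%. Repeated spacing is a property of tandem copies, and how reads of such copies were placed was not tested here. A set of 12865 CpG-dense tiles was chosen for a low level in the early DNMT3A and early DNMT3B knockouts. Their pooled level was 2.74%, 2.43% and 1.68% in the early DNMT3A, DNMT3B and double knockouts. It was 1.03%, 0.743% and 0.131% late and 1.04% in the CD184 library. Each early library thus lay above its late partner, although the choice favours low early levels. Whether such an offset enters the late minus early differences elsewhere was not tested.

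The genotype of the late library titled DNMT3B knockout is contradicted by its own labels. A mislabelled sample from DNMT3A knockout cells would lie near the early DNMT3A level where the early libraries differ. On a scale from 0 at the early DNMT3A level to 1 at the early DNMT3B level, its median position was 0.767 (bootstrap interval 0.761 to 0.774) over 24464 autosomal tiles that differed by 20 points, and 0.951 (0.940 to 0.962) over the 2604 autosomal tiles past the threshold. Bootstrap intervals here and in the next paragraph resample tiles as if independent, which neighbouring tiles are not, and measure no spread between libraries. The late DNMT3A knockout lay at 0.289 and 0.126 in the same tiles. These values argue against the DNMT3A genotype tag, and a hypothesis in line with them is that the title is right.

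Tiles higher at late passage in both single knockouts numbered 232, with levels near 40% in the 3 early libraries (39.3%, 40.3% and 38.4%) and 80.1%, 79.98% and 68.6% in the late ones. Gain of methylation by the DNMT3A or DNMT3B left in each single knockout would spare the double knockout. Yet 90.1% of these 232 tiles were higher there too. Tiles that rose in only 1 single knockout are left out of this set, so it cannot speak for a gain in those. Over all 1507 tiles higher in the late DNMT3A knockout, the double knockout went from 51.9% to 55.8%. Over all 848 tiles higher in the late library titled DNMT3B knockout, it went from 51.3% to 65.1%. A technical difference between the early and the later libraries may explain the 232 tiles. The double knockout's median rise there was 27.4 points (bootstrap interval 24.9 to 29.3), and the CD184 library also stood at 79.99%. Extra unmethylated reads from another copy in the early libraries are a candidate explanation of this kind: the early over late depth ratio, relative to tiles of the same CpG density, had a median of 1.64 (1.52 to 1.75), against 1.01 in tiles matched on reads and density. The labels name no batch, and a technical difference of this kind would follow the passage labels, so passage itself stays open too.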
